A study of Mus musculus with 6 samples.

How the data were processed

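Small RNA libraries were made by the submitters from total hippocampal RNA with the Illumina TruSeq small RNA protocol and sequenced on an Illumina HiSeq, per the labels. RNA from 3 mice was pooled in equal amounts for each library, and the labels call the 3 libraries of a genotype biological replicates. The design text of the series gives 12 mice per genotype, while 3 pools of 3 mice make 9. Group and replicate number were taken from the sample titles.

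Each deposited file lists the same 109108 features with a name, position and strand, a column of raw counts and a column of normalized counts. The raw column holds whole-number read counts per feature as deposited by the authors, with no scaling. The normalized column is a signal that the authors made by multiplying the raw counts of a library by 1 constant, which the deposited values themselves show, and it was used only to recover those constants. The submitters' processing notes name GRCm38 (mm10), CASAVA 1.8.2, BWA, SAMtools 0.1.18 and DESeq2 without saying what each was used for. The counter, its strand setting, the treatment of reads with several alignments and the annotation release are not given in the sources used here. Per the file headers, the column name of WT replicate 2 gives GRCm38, lane 4 and inserts of 18 to 50, and the other files give no such detail.

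What the counts hold was tested on the files. They list 2035 mature miRNA rows with 1900 names, small RNA genes, tRNAs and whole transcript spans with introns, and a read is counted in every feature that holds it. Of 884 transcript spans with at least 1000 counts, 596 had over 50% of their counts in short RNA rows inside them. Counting ignored strand: in 21 of 23 pairs of miRNA rows on opposite strands of 1 place, with at least 100 counts, the totals agreed within 1%. Reads of miRNAs with several loci looked evenly divided, since in 20 of 23 such miRNAs with at least 1000 counts the lowest locus had at least 90% of the highest. Values of such rows are therefore uncertain between loci and strands. Rows with identical counts in all 6 libraries and the same gene were counted once, which removed 13139 rows.

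RNA classes were taken from the names in the files and, for 68368 features, from matching coordinates in GENCODE M21 (GRCm38). The 12293 features that neither named were treated as transcript spans. Mature sequences, GC content and host genes of miRNA rows were taken from the same annotation and its transcripts. The class rules, the choice of the span with the most counts for each gene of an mRNA list, and the joining of miRNA rows that share a name or at least 10 nt of a place were made after the files were seen.

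The comparison used edgeR 4.0.16 in R 4.3.3: filterByExpr by group (minimum count 10), TMM over all tested features, glmQLFit with robust estimation and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the 6539 tested features and a threshold of 0.05. The standard error of a log2 change was derived from the F statistic. CPM values refer to the summed feature counts after TMM scaling and not to reads. These sums were 63797625, 74809070 and 67813046 in WT replicates 1, 2 and 3, and 55101387, 77428956 and 65054406 in Dicer1-ifKO replicates 1, 2 and 3, of which miRNA rows held 2724752, 2889715, 3179363, 2318205, 2739366 and 2384984. The median miRNA change and the shares of counts by RNA class were compared by two-sided exact permutation of the 6 libraries, where 3 against 3 cannot give a p below 0.1. Molecular identifiers are not given in the sources used here.

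The test, the 20 gene lists, the named features and most alternatives were fixed before the data were examined. The named features were the 10 largest falls and 10 largest rises among miRNA rows past the threshold with a mean of at least 50 counts per library and no overlap between groups, the 10 most abundant miRNAs, up to 3 of the most abundant members of each list, 5 falls and 5 rises among other features by the same rule, and Dicer1. Lists with at least 3 tested members (15 of 20) were compared with the other tested miRNAs or spans by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. List members also occur in more than 1 cell type, and the lists were drawn up from general knowledge and not from these libraries. The values of 1 list member are not reported here.

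Alternatives were other scalings, DESeq2 1.42.0, other count filters, a fit of the miRNA rows alone, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were the authors' size factors, TMM over snoRNA rows, a fit of the short RNA classes alone, merged loci, removal of a GC trend fitted by loess (span 0.75) to the miRNA rows not called, the subtraction of miRNA reads from other features, and shares of the short RNA classes alone. The miRNA counts of libraries of 1 genotype differed by more than counting noise (chi-square over degrees of freedom from 21.6 to 66.1). This shows only that these are not repeat reads of 1 library, and the libraries were taken as replicates because the labels call them so.

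The fit was tested on simulated counts for this comparison, with the means, library sizes and dispersions of the 6539 tested features and 200 changed features in each of 10 runs. It called 1.19% of features changed by 0.5 on the log2 scale, 24.5% of those changed by 1 and 64.9% of those changed by 1.5, with 0 calls of the wrong sign and 8.4% of all calls false. In 10 runs with no change the most calls in a run were 6. A simulated list of 70 miRNA rows moved by -0.5 was called by camera at an unadjusted p of 0.05 in 10 of 10 runs, and with nothing moved in 0 of 10. The simulated rows were independent of each other, whereas the estimated correlation of the Dlk1-Dio3 list in the data was 0.36. These runs therefore do not measure false calls of lists whose members move together. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.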

Results

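Small RNA of the hippocampus was sequenced in 6 libraries from male C57BL/6 mice aged 3 months. All mice carried floxed Dicer1 alleles and received tamoxifen 3 weeks before the tissue was taken. Dicer1 encodes the ribonuclease that cuts precursor hairpins into mature miRNAs. In 3 libraries the mice also carried the CaMKIIa-creERT2 transgene, a tamoxifen-inducible recombinase expressed in excitatory forebrain neurons (Dicer1-ifKO), and in the other 3 they did not (WT). Each library held RNA pooled from 3 mice, so that 9 mice of each genotype entered these libraries, and the p-values measure the spread between pools. The miRNA features held 2318205 to 3179363 counts per library. The counts of all features summed to 55101387 to 77428956, but a read is counted in every feature that holds it, so these sums are not read depth.

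The comparison asks how small RNAs of the adult hippocampus changed after Dicer1 was inactivated in these neurons. The targeted gene itself was covered by few reads. The Dicer1 span (chromosome 12, 104687742 to 104751952, minus strand, GRCm38) held 45, 33 and 47 counts in WT replicates 1, 2 and 3, and 37, 32 and 35 in Dicer1-ifKO replicates 1, 2 and 3. Its level was 0.87 ± 0.17 CPM in WT and 0.75 ± 0.15 CPM in Dicer1-ifKO (SD, n = 3 each). The log2 change of -0.24 ± 0.24 (SE) did not pass edgeR's quasi-likelihood test (adjusted p = 0.93). These reads are fragments over the whole gene and do not resolve a floxed exon, so the count checks no genotype label.

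A set of miRNAs fell in Dicer1-ifKO hippocampus, and none rose. Of 546 tested miRNA rows, which stand for 482 distinct miRNAs, 36 rows (34 distinct miRNAs, with the adjacent miR-3102 rows counted apart) were lower and 0 were higher (edgeR quasi-likelihood test, Benjamini-Hochberg over 6539 features, adjusted p of 0.05). The falls ran from 0.61 to 1.63 on the log2 scale, and their median was -1.07. The largest was that of miR-222-3p, from 251 ± 17.8 CPM in WT to 81.0 ± 8.42 CPM in Dicer1-ifKO (SD, n = 3 each), a ratio of 0.32 (log2 -1.63 ± 0.14 SE, adjusted p = 3.2e-04 by edgeR). Its cluster neighbour on chromosome X, miR-221-3p, fell from 89.6 ± 9.41 to 45.7 ± 5.94 CPM (edgeR adjusted p = 0.013).

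**Figure D1:**
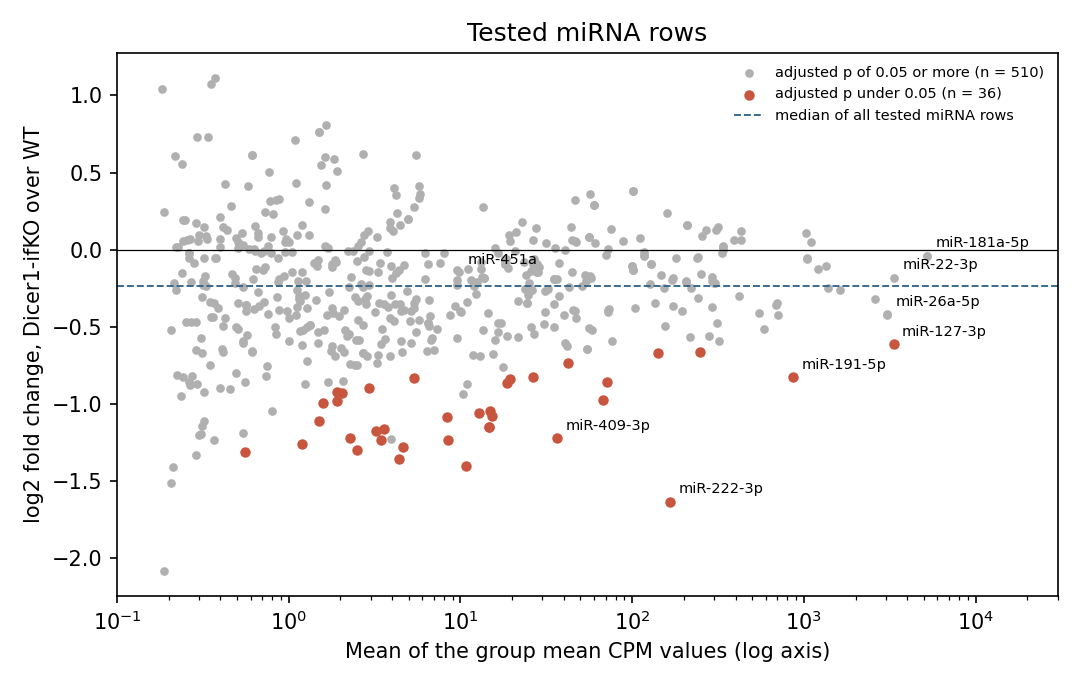
Each point is 1 of 546 tested miRNA rows, with the mean of the group mean CPM values on a log axis and the log2 fold change of Dicer1-ifKO over WT (n = 3 each) on the other, all scaled by TMM over all features. The 36 rows with an adjusted p under 0.05, in red, all lie below 0, and the dashed line marks the median of all tested rows at -0.24, which moved to 0.0013 when the miRNA rows set the scaling.

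Among called miRNAs with a mean of at least 50 counts per library, the largest falls besides that of miR-222-3p were those of miR-6944-3p (log2 -1.40), miR-672-5p (-1.36), miR-3102-3p.2-3p (-1.30), miR-431-5p (-1.28), miR-665-3p (-1.26), miR-187-3p (-1.24), miR-3102-3p (-1.23), miR-760-3p (-1.22) and miR-409-3p (-1.22). Among these, miR-409-3p was abundant, at 51.0 ± 4.03 CPM in WT and 21.9 ± 2.35 CPM in Dicer1-ifKO (SD, n = 3 each). Several lie inside protein-coding genes: in GENCODE M21, miR-6944-3p lies in an intron of Dbn1, miR-672-5p in an intron of Nexmif, and both miR-3102 products in an exon of Arhgef17. The adjacent rows of miR-3102-3p and miR-3102-3p.2-3p held 981 and 709 counts, while the Arhgef17 span around both held 1289. The rows thus appear to share reads, so their falls are not separate results. miR-222-3p lies outside annotated protein-coding genes, at chromosome X, 19146903 to 19146923 on the minus strand, with the mature sequence AGCTACATCTGGCTACTGGGT in DNA letters. miR-409-3p (GAATGTTGCTCGGTGAACCCCT) lies at chromosome 12, 109743204 to 109743225 on the plus strand, in an intron of the long noncoding RNA Mirg. Left out in turn, no library ended the call of miR-222-3p. Without Dicer1-ifKO replicate 2 the other 9 were not called, and without Dicer1-ifKO replicate 3 neither were miR-672-5p, miR-665-3p, miR-187-3p and the miR-3102 products. miR-665-3p was also not called without WT replicate 3, nor the miR-3102 products without WT replicate 2 or Dicer1-ifKO replicate 1. On library totals alone, miR-665-3p, miR-3102-3p.2-3p and miR-3102-3p were not called (edgeR adjusted p = 0.11, 0.056 and 0.068). With the GC trend removed, miR-665-3p was not called (edgeR adjusted p = 0.073). With the replicate number as a block, miR-672-5p, miR-431-5p, miR-187-3p, miR-409-3p, miR-760-3p, miR-665-3p and the miR-3102 products were not called. Their edgeR adjusted p ran from 0.057 to 0.13. In all 36 rows the CPM values of the groups did not overlap. Over all tested rows, 185 lower and 11 higher rows had no overlap, where chance gives 10%.

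**Figure D2:**
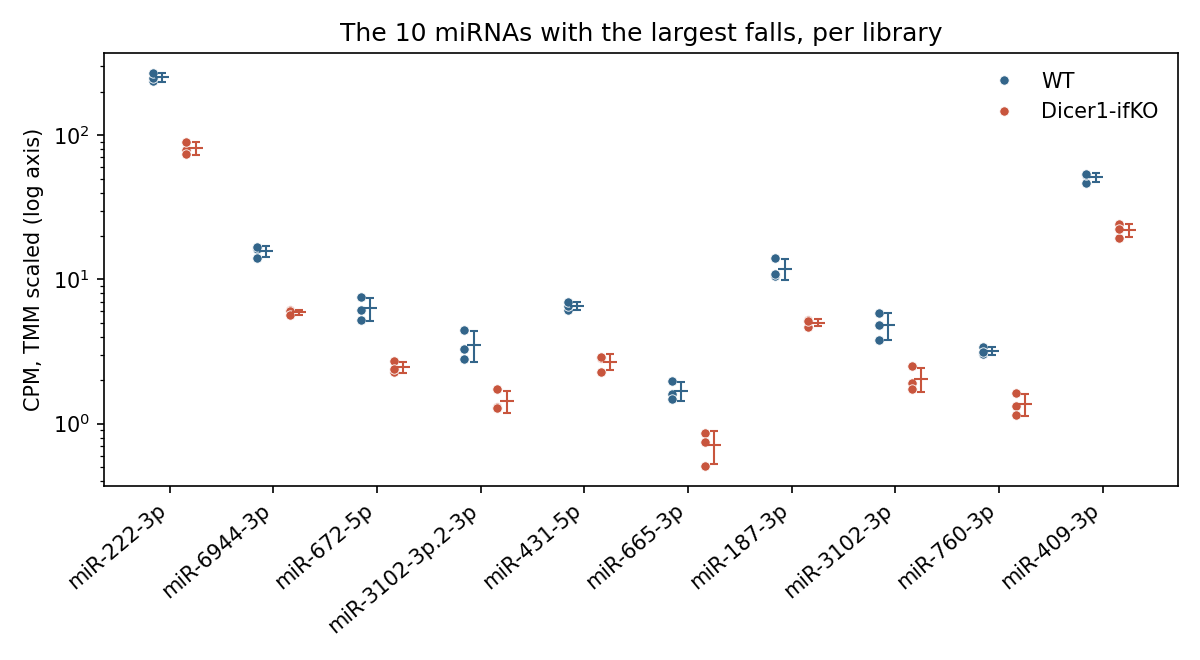
Points are single libraries (WT in blue, Dicer1-ifKO in red, n = 3 each) for the 10 miRNAs with the largest falls among those with a mean of at least 50 counts, as TMM-scaled CPM on a log axis, with the mean and SD beside them. In each miRNA every Dicer1-ifKO library lies below every WT library, as for miR-222-3p with means of 251 and 81.0 CPM.

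Most of the abundant hippocampal miRNAs did not pass the test. Of the 10 most abundant, only miR-127-3p fell, from 4036 ± 302 to 2635 ± 145 CPM (SD, n = 3 each; log2 -0.61 ± 0.12 SE, edgeR adjusted p = 0.033), and of the 6 libraries only WT replicate 1 could be left out without losing that call. It was also not called with the GC trend removed (log2 -0.53, edgeR adjusted p = 0.084). The most abundant, miR-181a-5p, stood at 5311 ± 449 CPM in WT and 5171 ± 407 CPM in Dicer1-ifKO, a log2 change of -0.04 ± 0.12 (SE). The log2 changes were -0.18 for miR-22-3p, -0.42 for miR-26a-5p, -0.32 for miR-125a-5p, -0.26 for miR-434-3p, -0.11 for miR-29a-3p, -0.25 for miR-27b-3p, -0.13 for miR-30d-5p and 0.05 for miR-92b-3p. Among abundant miRNAs outside that group, miR-191-5p fell from 1109 ± 103 to 624 ± 17.0 CPM (SD, n = 3 each; edgeR adjusted p = 0.0097), and miR-378a-3p fell from 92.1 ± 9.75 to 50.8 ± 0.63 CPM (edgeR adjusted p = 0.015). miR-191-5p, miR-378a-3p and miR-221-3p were chosen after their values were seen. Without WT replicate 1, miR-26a-5p was also called.

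The number of miRNAs that passed rested on single libraries and on the scaling. It was 70 without WT replicate 1, 13 without WT replicate 2, 14 without WT replicate 3, 19 without Dicer1-ifKO replicate 1, 1 without Dicer1-ifKO replicate 2 (miR-222-3p) and 8 without Dicer1-ifKO replicate 3, and all of these were lower rows. With the scaling set by the miRNA rows, which moved their median from -0.24 to 0.0013 and that of the other features from -0.03 to 0.20, 8 rows were lower and 0 higher. Fitted without the other features, 36 miRNA rows were lower and 11 higher. In the fit of all features, 170 rows were lower and 11 higher at an unadjusted p of 0.05, adjustment over the miRNAs alone gave 104 lower and 1 higher, and DESeq2 gave 32 lower and 0 higher. Across miRNA rows, which are not independent replicates, the log2 change went down with the GC content of the miRNA (Spearman's rho -0.31 over 546 rows), and this rested on WT replicate 2 and Dicer1-ifKO replicate 1, without which rho was -0.045.

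**Figure D3:**
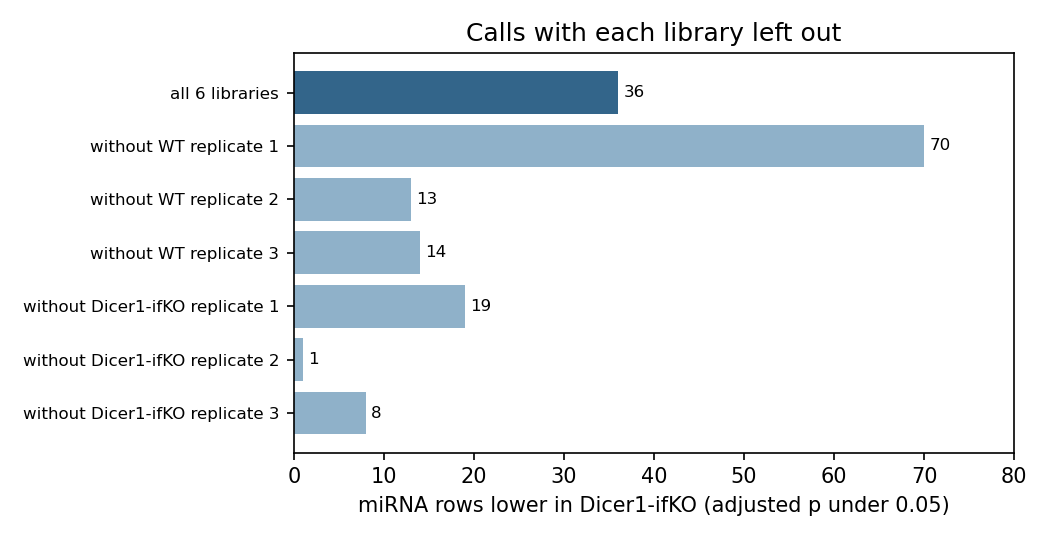
Bars give the number of miRNA rows lower in Dicer1-ifKO at an adjusted p under 0.05, with all 6 libraries and with each library left out in turn. The count was 36 with all libraries, 70 without WT replicate 1 and 1 without Dicer1-ifKO replicate 2.

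As a group, all tested miRNA rows had a median log2 change of -0.24, and 75.5% lay below 0, against a median of -0.03 and 55.1% for the other features. The per-library median deviation of the miRNAs lay between -0.0042 and 0.33 in WT and between -0.23 and 0.0039 in Dicer1-ifKO, which gave a two-sided exact permutation p of 0.2, where 3 against 3 libraries cannot go below 0.1. The median log2 change was 0.0013 when the miRNA rows set the scaling. miRNA features took 4.27% ± 0.41 of the summed counts in WT and 3.80% ± 0.36 in Dicer1-ifKO (SD, n = 3 each; exact permutation p = 0.2, adjusted p = 1 over 8 classes). snoRNA features took 14.3% ± 0.36 and 14.6% ± 0.16 (exact permutation p = 0.4). WT replicate 1 stood apart from the other libraries, with 1.21% of its counts in rRNA features against 0.51% to 0.74% elsewhere, and 0.31% in mitochondrial tRNA features against 0.11% to 0.18%. No class differed between the genotypes by this test.

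The miRNAs of the maternally expressed Dlk1-Dio3 cluster, an imprinted region of chromosome 12 that is transcribed in neurons, lay mostly below 0. Of 70 tested rows, 66 lay below 0, and the median log2 change was -0.47. Of all tested miRNA rows 75.5% lay below 0, with a median of -0.24. In this list 13 rows fell and 0 rose, and 30 fell when adjusted over the list alone. The 13 were miR-127-3p, miR-300-3p, miR-370-3p, miR-409-3p, miR-410-3p, miR-431-5p, miR-485-3p, miR-495-3p, miR-540-3p, miR-543-3p, miR-665-3p, miR-673-5p and miR-770-3p. Of the most abundant members, miR-434-3p (1780 ± 117 against 1487 ± 36.5 CPM) and miR-381-3p (363 ± 24.2 against 262 ± 22.3 CPM, SD, n = 3 each) did not pass. The list was lower than the other miRNAs by camera (limma, adjusted p = 0.0017 over 15 lists), and this was lost at an adjusted p = 0.90 with an estimated correlation. It was not called by limma's fry either (adjusted p = 0.11). With the scaling set by the miRNA rows, 51 of the 70 rows lay below 0 (median -0.23) and 2 fell.

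Of the neuron-enriched miRNAs, a few fell and none rose. miR-129-5p, from 2 loci, fell: its locus on chromosome 6 went from 19.9 ± 0.32 to 9.66 ± 0.87 CPM (SD, n = 3 each; edgeR adjusted p = 0.0077). The locus on chromosome 2 shares its reads with the opposite-strand miR-129b-3p, so these rows cannot be told apart. miR-212-3p, which shares a transcript with miR-132, fell from 52.9 ± 5.04 to 31.8 ± 2.93 CPM (edgeR adjusted p = 0.048). Among members that did not pass, miR-9-5p had a log2 change of 0.02 ± 0.16 (SE), and the chromosome 2 locus of miR-124-3p stood at 118 ± 17.5 and 117 ± 17.3 CPM (SD, n = 3 each; log2 -0.01). miR-128-3p (log2 -0.43) and miR-132-3p (-0.37) did not pass either. Of the 38 rows of the list, 4 fell and 0 rose, and 13 fell when adjusted over the list alone. The list did not differ from the other miRNAs (camera adjusted p = 0.67), and with the scaling set by the miRNA rows 2 rows fell and its median of -0.30 was -0.07.

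The miRNAs listed as made without Drosha, from mirtrons, capped or snoRNA-derived hairpins that still need Dicer, had a median of -0.55. miR-484 fell from 33.7 ± 2.28 to 19.0 ± 1.40 CPM (SD, n = 3 each; edgeR adjusted p = 0.023), a call kept only when WT replicate 1 was the library left out, and miR-877-5p and miR-1839-3p fell with it, while miR-320-3p (-0.40) and miR-1839-5p (-0.25) did not pass. Of the 11 rows, 3 fell and 0 rose, and 7 fell when adjusted over the list alone. On library totals alone, and with the scaling set by the miRNA rows (median -0.31), 0 rows of this list fell by edgeR, and 1 fell with the GC trend removed. Camera did not separate the list from the other miRNAs (adjusted p = 0.13, and adjusted p = 0.68 with an estimated correlation). Limma's fry, which tests whether the members move one way without comparing them with other miRNAs, gave an adjusted p of 0.0099. miR-451a, whose hairpin is cut by Ago2 and not by Dicer, stood at 10.3 ± 1.87 and 9.29 ± 0.85 CPM (log2 -0.15 ± 0.18 SE), and miR-486-5p, another miRNA of red blood cells, at 105 ± 6.34 and 96.0 ± 9.09 CPM. Of the 5 erythrocyte rows 0 fell and 0 rose over all features or adjusted over the list alone (edgeR), and camera gave an adjusted p of 0.23, with a median of -0.11 and a mean of 0.08. With the scaling set by the miRNA rows the erythrocyte median turned to 0.12, and miR-451a to 0.08.

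Of the 6 miRNA lists for cell types outside the recombined neurons, those of microglia and leukocytes, vessels and oligodendrocytes lay above the other miRNAs by camera with its preset correlation, although no member passed in the fit of all features. None of these 3 calls held with an estimated correlation (camera adjusted p = 0.68, 0.73 and 0.68, in the same order) or by fry (adjusted p = 0.47, 0.68 and 0.68). The astrocyte, erythrocyte and choroid plexus lists were not called at all. Medians were 0.24 for the microglia and leukocyte list (5 rows), 0.15 for the vascular list (7 rows) and 0.11 for the oligodendrocyte list (10 rows), against -0.24 for all tested miRNA rows. With the scaling set by the miRNA rows they were 0.48, 0.41 and 0.35, against 0.0013. In each list 0 rows fell and 0 rose over all features, and likewise adjusted over the list alone (edgeR), while in the fit of miRNA rows alone miR-150-5p and miR-142-5p were called higher (edgeR adjusted p = 0.034 and 0.042). miR-150-5p, of lymphocytes, had means of 147 CPM in WT and 173 CPM in Dicer1-ifKO, a log2 change of 0.24 ± 0.14 (SE, n = 3 each), and the myeloid miR-142-5p and miR-146a-5p had log2 changes of 0.18 and 0.0074. miR-143-3p of smooth muscle had 0.15, the rows of endothelial miR-126 0.08 and 0.38, and the rows miR-338-3p, miR-219b-5p and miR-338-5p of the oligodendrocyte list 0.16, 0.05 and -0.09. The miR-219b-5p row held 13235 counts and the opposite-strand miR-219a-2-3p row 13132, so these rows cannot be told apart. Camera placed all 3 lists above the other miRNAs, with adjusted p = 0.0017 for microglia and leukocytes, 0.0067 for vessels and 0.0029 for oligodendrocytes. In the same order, the lists had means of 0.52, 0.18 and 0.29 and held 4, 5 and 5 distinct miRNAs, so some reads counted more than once. In the microglia and oligodendrocyte lists every row named here lay below the mean, so rows not named raised it. The opposite-strand rows miR-142-3p and miR-142b held only 103 and 98 counts over all libraries. With rows that share reads merged, 3 rows matched the oligodendrocyte list, although it held 5 distinct miRNAs, and its camera adjusted p was 0.14. Joined rows were named after the row with the most counts. miR-3065-3p held 5182 counts against 5179 for miR-338-5p, and miR-3065-5p held 59074, as did miR-338-3p. Members can thus drop out by name, so this value is not one for the same list. In the lists so far, miR-129-5p, miR-212-3p, miR-124-3p, miR-877-5p, miR-1839-3p and called Dlk1-Dio3 members outside the rule for named miRNAs were named after their values were seen.

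The remaining miRNA lists did not differ from the other miRNAs by camera, and 0 of their rows fell or rose over all features (edgeR). For the let-7 family the median over 25 rows was -0.18, with 1 row lower adjusted over the list alone and an adjusted p of 0.38, and the median turned to 0.06 with the scaling set by the miRNA rows. Its abundant members let-7c-5p (-0.35), let-7d-5p (-0.30) and let-7f-5p (0.12) did not pass. The astrocyte-enriched list, with miR-26a-5p, miR-29a-3p and miR-29c-3p (log2 0.05) as its most abundant members, had a median of -0.10 over 14 rows, 3 rows lower adjusted over the list alone, and an adjusted p of 0.80, and the median turned to 0.14 under that scaling. The proliferation-linked miR-17-92 cluster and its paralogs had a median of -0.11 over 13 rows, with 0 rows past the test adjusted over the list alone and an adjusted p of 0.38, and its median turned to 0.15 under that scaling. Its abundant members miR-92a-3p, miR-25-3p and miR-93-5p had log2 changes of 0.09, -0.26 and 0.06. The choroid plexus and epithelial list had a median of -0.43 with all 8 rows below 0, and an adjusted p of 0.93, and under that scaling a median of -0.18 with 5 rows below 0. Its most abundant member, miR-204-5p, stood at 332 ± 11.8 and 225 ± 9.43 CPM (edgeR adjusted p = 0.067), was called without WT replicate 1, and was the 1 row lower adjusted over the list alone. miR-200b-3p and miR-429-3p had log2 changes of -0.65 and -0.30.

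**Figure D4:**
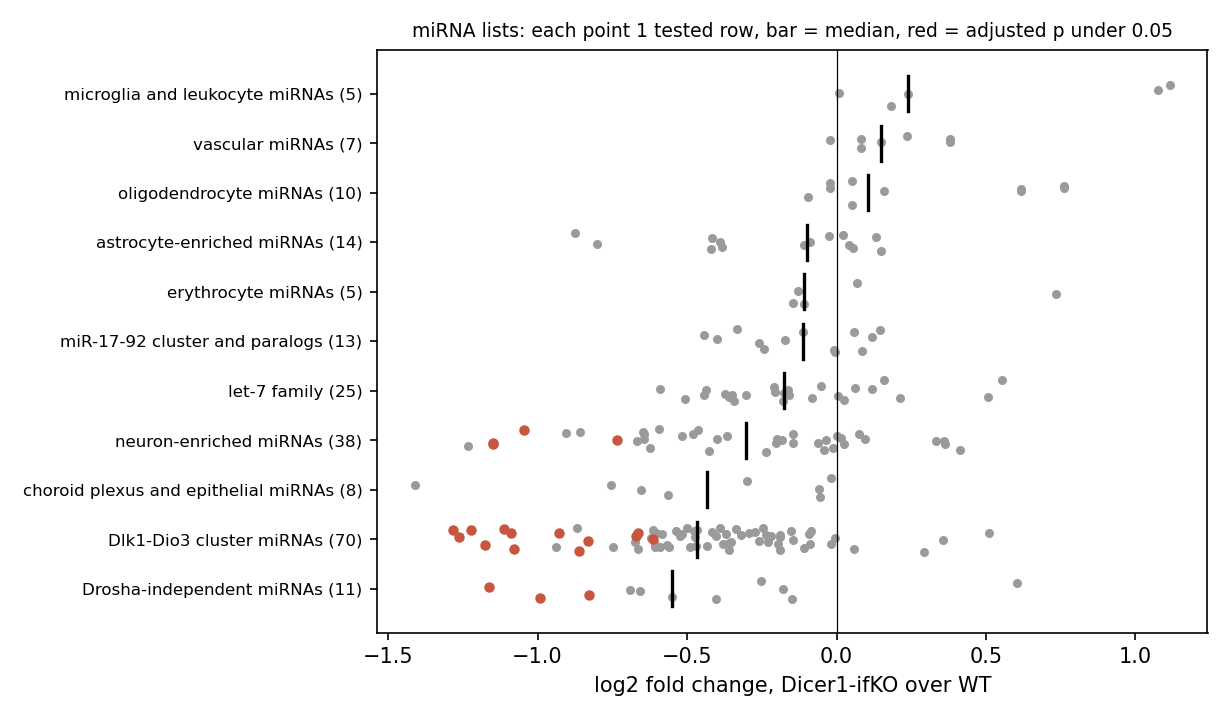
Each point is 1 tested row of a miRNA list, placed by its log2 fold change of Dicer1-ifKO over WT (n = 3 each, TMM over all features), with red for an adjusted p under 0.05, a black bar at the median and the number of rows in brackets. Medians ran from -0.55 for the Drosha-independent list and -0.47 for the Dlk1-Dio3 cluster to 0.24 for microglia and leukocytes, and the medians of the let-7 family, astrocyte, miR-17-92 and erythrocyte lists turned to 0.06, 0.14, 0.15 and 0.12 when the miRNA rows set the scaling.

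No mRNA span of the cell type lists passed the test, and several lists had too few spans with enough counts for a list test. For excitatory neurons, the spans of Camk2a (2.66 ± 0.37 and 2.29 ± 0.37 CPM, SD, n = 3 each), Gria1 (log2 0.14) and Grin2b (-0.08) did not pass, and the 7 tested spans had a median of -0.08 (camera adjusted p = 0.93). The 3 astrocyte spans Slc1a2 (0.18), Slc1a3 (-0.26) and Aldoc (0.05) had a camera adjusted p of 0.74, with a median of 0.05 and a mean of -0.0061. The 3 oligodendrocyte spans, with Mbp (-0.09) and Mobp (-0.34), had 0.67. The 4 spans of the miRNA pathway, among them Dgcr8 (-0.33), Tnrc6b (-0.03) and Dicer1, had a median of -0.13 and 0.74. miRNA rows inside the span held 224 of 257 counts of Dgcr8, 148 of 704 of Camk2a and 23 of 197 of Tnrc6b, so the value of Dgcr8 is mostly one of miRNA reads. With the scaling set by the miRNA rows, the medians of the excitatory neuron, oligodendrocyte and miRNA pathway spans turned to 0.15, 0.14 and 0.10. Gad1 (-0.75), Cx3cr1 (0.78) and Pecam1 (0.27) were the 1 tested span of the interneuron, microglia and endothelial lists, and none passed, although the groups did not overlap for Cx3cr1, where chance gives 10%. The choroid plexus mRNAs had 0 spans with enough counts to test. In each of these lists 0 spans fell and 0 rose, over all features or adjusted over the list alone (edgeR).

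Features other than miRNAs gave 16 lower calls and 1 higher call. Many of the 16 were overlapping spans of 1 gene that hold the same reads, for Dbn1, Sorcs2, C77370, Klhl3 and Ppargc1b. They are therefore not separate results. The lower ones with the largest falls were spans of Dbn1 (log2 -1.38), Arhgef17 (-1.16), C77370 (-1.08) and Klhl3 (-1.02) and a tRNA pseudogene on chromosome 5 (-0.98). In 15 of the 16 over 90% of the reads lay in miRNA rows inside the feature, and in the other 89.5%, so that the Dbn1 span carried the reads of miR-6944-3p and that of Klhl3 those of the miR-874 hairpin. With these reads subtracted, 13 of the 16 had too few counts to test and none of the 16 was called. The tRNA pseudogene and miR-7689-3p hold the same 545 reads, whose origin is uncertain. The 1 higher feature was the Fam176a-002 span (chromosome 6, 82041688 to 82047150), at 0.73 ± 0.16 CPM in WT and 1.56 ± 0.11 CPM in Dicer1-ifKO (SD, n = 3 each; log2 1.10 ± 0.22 SE, edgeR adjusted p = 0.034). It held no miRNA reads, 2 longer spans of the gene had log2 changes of 0.28 and did not pass, and it was called in 1 of 6 fits with a library left out, that without WT replicate 1. It was not called on library totals alone (edgeR adjusted p = 0.059), by DESeq2, or in the fit after the subtraction of miRNA reads. Over all features, 52 were lower and 1 higher, and the number of changed features was 143 without WT replicate 1, 16 without WT replicate 2, 18 without WT replicate 3, 24 without Dicer1-ifKO replicate 1, 1 without Dicer1-ifKO replicate 2 and 11 without Dicer1-ifKO replicate 3.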

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

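The authors' size factors, TMM over snoRNA rows, the fit of the short RNA classes, merged loci, GC removal and shares of the short RNA classes were chosen after the data were seen. Higher miRNA rows were called only when the miRNA rows were fitted alone (11) or adjusted alone (1). The changed features numbered 53, and 23 on library totals alone, 12 with TMM over miRNA rows, 33 with TMM over non-miRNA rows and 1 to 143 with a library left out. The changed miRNAs numbered 36, and 16, 8 and 23 under the same scalings, 105 adjusted over miRNAs alone and 1 to 70 with a library left out, and the settings other than these and the replicate block stayed within 1.5 times. The cause was not tested, except that TMM over miRNA rows sets their median near 0 by construction. There the median miRNA change reversed to 0.0013, in the fit of miRNA rows alone to 0.00041, and Dicer1 to 0.0054 (edgeR adjusted p = 1.0), while leaving out a library gave medians of -0.34 to -0.11. With the replicate number as a block, 6 features and 3 miRNA rows were called, and the 4 list calls stayed. Among the named features not called there were miR-127-3p, miR-484, Fam176a-002 and most of the miRNAs with the largest falls. Same-numbered libraries 1, 2 and 3 had correlations of -0.18, 0.08 and -0.16 over all features and -0.05, 0.26 and -0.26 over miRNA rows. Not every library correlated best with its own number. With 3 libraries per group these values cannot decide whether the numbers pair the libraries. Of 4 lists called by camera, 0 were called with an estimated correlation and 0 by fry, which called 1 other list, the Drosha-independent miRNAs. The miRNA share differed by -0.47 percentage points over all features and -2.09 over the short RNA classes.

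Features that did not pass the test changed sign as follows. On library totals alone the log2 changes were 0.021 for Tnrc6b and 0.015 for miR-181a-5p, and under the block -0.021 for miR-146a-5p. With the GC trend removed they were -0.11 for miR-29c-3p, -0.12 for let-7f-5p, -0.085 for miR-146a-5p, -0.031 for miR-142-5p, -0.16 for miR-9-5p and -0.081 for miR-126b-5p. With each library left out in turn, values ran from -0.40 to 0.13 for Slc1a3, -0.14 to 0.53 for Aldoc, -0.14 to 0.028 for Grin2b, -0.12 to 0.055 for Tnrc6b, -0.22 to 0.039 for Mbp and -0.012 to 0.54 for Pecam1. They ran from -0.17 to 0.26 for miR-29c-3p, -0.23 to 0.14 for miR-146a-5p, -0.069 to 0.22 for miR-9-5p, -0.14 to 0.27 for miR-219b-5p, -0.058 to 0.13 for miR-92b-3p, -0.12 to 0.44 for let-7f-5p, -0.13 to 0.30 for miR-93-5p, -0.11 to 0.063 for miR-181a-5p, -0.0037 to 0.45 for miR-338-3p, -0.073 to 0.27 for miR-126b-5p and -0.0015 to 0.69 for miR-126b-3p. With few counts, changes of low features are not resolved, as for Dicer1 with 229 counts over 6 libraries.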

Other observations

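The tests of GC content, of scaling and of miRNA reads inside other features were chosen after the results were seen, and the tests of neuron loss, of hairpin arms and of other splits were fixed before. Set against the other miRNAs, in the fit of miRNA rows alone, 11 rows were higher in Dicer1-ifKO, and their log2 changes ran from 0.41 to 1.28. The value of 1.28 is that of miR-6516-3p, which held only 52 counts over all libraries. They were miR-6516-3p, miR-193a-3p, miR-101a-5p, miR-139-3p, miR-101c, miR-135a-5p, miR-135a-2-3p, miR-540-5p, miR-34c-5p, miR-150-5p and miR-142-5p, named after their values were seen. miR-34c-5p stood at 662 ± 63.0 CPM of miRNA counts in WT and 971 ± 171 CPM in Dicer1-ifKO (SD, n = 3 each; edgeR adjusted p = 0.038). miR-150-5p stood at 2380 ± 281 and 3322 ± 299 CPM (SD, n = 3 each; edgeR adjusted p = 0.034). Both arms of the hairpin of miR-540, in the Dlk1-Dio3 cluster, were called in opposite directions in that fit, miR-540-5p at 0.75 and miR-540-3p at -0.84. In the fit of all features these 11 were not called, and miR-540-5p had a log2 change of 0.51 (edgeR adjusted p = 0.59).

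The fall of miRNAs in Dicer1-ifKO had a median log2 change of -1.07 over the 36 called rows (median SE 0.17). With the GC trend of each library removed it was -0.98 (95% bootstrap interval over rows -1.10 to -0.89, median SE 0.18). With TMM over miRNA rows it was -0.83 (-0.94 to -0.70, median SE 0.17). Both lay below a bound of -0.5 that was set after the results were seen. The 36 rows were chosen for their falls in these same libraries. Scaling by the miRNA rows moves all of them nearly alike, and the GC trend was fitted to the rows not called. Neither test can therefore decide whether scaling or GC content caused the falls. Only 24 and 8 of the 36 rows stayed called, for reasons not tested. The 7 excitatory neuron mRNA spans had a median of -0.08, and the interval (-0.22 to 0.14) resampled spans and not mice. The called miRNAs were chosen for their falls, so the smaller change of these spans is no fair comparison with them. Without such a choice, all tested miRNA rows had a median of -0.24 and the neuron-enriched list one of -0.30. The spans hold few reads, which are mRNA fragments and for Camk2a partly miRNA reads, so a loss of these neurons was not settled. Of the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05, 1, the genotype split, gave the most miRNA rows, 36 against at most 0 in another split; for all features the values were 53 and 8, and for list calls 4 and 3. Lower Dicer activity in the recombined neurons, which the design names, may underlie the falls and stays open as untested. GC content, scaling and a loss of neurons stay open too. The GC slopes of WT replicate 2 and Dicer1-ifKO replicate 1 were the steepest. Without these libraries rho of GC and log2 change was -0.045, and the 36 rows had a median of -1.05 with 1 row called.

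The 16 other features that were lower held mostly reads counted in miRNA rows inside them, 89.5% or more in each. With these reads subtracted, 16 of the 16 were no longer called, 13 of them for want of counts. Given those shares, this outcome was nearly fixed in advance. For the Arhgef17 span the miRNA rows inside summed to 1745 counts against 1289 of the span, so some reads were subtracted more than once. What remains of the host transcripts was not resolved. No biological explanation was tested for them.

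A hypothesis fixed before the data were examined held that the less abundant arm of a hairpin would fall more than the abundant arm, which Argonaute proteins protect. Over 135 hairpins with both arms tested, the median difference of minor minus major arm was -0.0034 (95% bootstrap interval -0.082 to 0.075), and the sign-flip permutation p was 0.86 over 100000 resamples, with the minor arm lower in 70 hairpins. The interval and the p resample hairpins of the same libraries, and so do not measure the spread between pools. The interval did not reach -0.24, the median change of the major arms, a value that depends on the scaling. Among the 65 hairpins whose minor arm was not richer in GC the median difference was 0.11 (-0.0017 to 0.22), and with no difference between arms the part of GC content cannot be told apart. Across hairpins, which are not independent replicates, the log2 changes of the arms had a Spearman's rho of 0.37.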
